A study of Caenorhabditis elegans with 4 samples.

How the data were processed

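Per the labels, total RNA of synchronized mid-L4 Caenorhabditis elegans was isolated with Tri-reagent and purified on RNeasy columns. From 100 ng, cRNA was made by linear amplification and labelled with Cy3 or Cy5. Each of the 4 arrays compared the double mutant isp-1(qm150);ceh-23(ms23) with isp-1(qm150). The labels give 3 biological replicates and a technical dye flip of replicate 1. The double mutant was in Cy5 on the dye-flip array of replicate 1 and in replicate 2, and in Cy3 on the first array of replicate 1 and in replicate 3. Per the file headers, the arrays were scanned and quantified by the authors with Agilent Feature Extraction 10.5.1.1 under protocol GE2_105_Dec08, and the array design names the genome build ce4. The barcodes and positions in the files place both arrays of replicate 1 on one slide and replicates 2 and 3 on another, with 1 scan per slide.

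The deposited scanner files hold, per the file headers, the median pixel intensity of each spot and of its local background in each channel, which is neither background-subtracted nor normalized. They also hold background-subtracted and dye-normalized intensity values and a log10 ratio of processed Cy5 over Cy3 that the authors obtained from Feature Extraction. The remaining deposited columns used here are flags of 0 or 1, other than intensities, for spots well above background, saturated spots and outlier spots. The deposited series table gives log10 ratios of Cy5 over Cy3, not turned for the dye. On each array they differed from the scanner's log10 ratio by less than 0.005, and their median was 0. Intensity values and flags served for the fit, and the deposited log10 ratios served as alternatives.

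Choices of filter, normalization, tests, gene lists, named genes and alternatives were fixed before the data were examined, except where stated. The plan had assumed a mean signal column. The files hold the median signal and a background-subtracted mean, so the median signal was used and the mean became an alternative. In R 4.3.3 with limma 3.58.1, background was corrected by normexp with an offset of 50 and each array was normalized by loess with control spots at weight 0. Outlier spots were left out, which were 10 and 8 on the arrays of replicate 1, 496 in replicate 2 and 143 in replicate 3. Each log2 ratio was turned to double mutant over isp-1 by the dye in the labels. Before normalization the median log2 ratios were 0.09 on the dye-flip array, -0.25 on the first array of replicate 1, -1.29 in replicate 2 and 1.47 in replicate 3. Afterwards, over the probes kept, they lay between -0.04 and 0.01. Probes were kept if well above background in at least 1 genotype in all 3 replicates, where either array sufficed in replicate 1. The ceh-23 and isp-1 probes were taken from the same model fitted to all probes without this filter, with p adjusted over those probes.

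Probes were named through the RefSeq gene table of assembly WBcel235, since the files give sequence names and accessions only. Of 43803 spots, 35017 were named by sequence name, 356 by accession, and 8430 were not named. Because the design and the table are on different builds, positions were used only to say which genes neighbour each other and which lie within 2 Mb of ceh-23. The filter kept 26246 of 43603 distinct probes, of which 23863 were named, and 13685 genes had values in all replicates. A gene's value was the mean over its kept probes, with 9730 genes on 1 probe and 3955 on several. Of the latter, 7 had probes with opposite mean ratios that were each past a fixed minimum size. Smaller disagreements in sign were not counted.

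The arrays of replicate 1 were averaged and the 3 replicate values tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The prior had 4.10 degrees of freedom and the total was 6.10. SD values are over the 3 replicates. Concordant genes were those with the same sign on all 4 arrays and a mean ratio of at least 1.5-fold. Lists of at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 47 lists, and again with an estimated correlation and with fry. Each list was also counted at an adjusted p of 0.05 adjusted over the list alone. Places of changed genes were compared by two-sided Fisher's exact test, with concordant genes in place of changed ones where fewer than 20 genes changed. The genes named were ceh-23 and isp-1, the 10 highest and 10 lowest mean ratios among genes past the threshold with the same sign on all 4 arrays, and up to 4 members of each list with the smallest unadjusted p.

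Alternatives were the scanner's own log ratio, the series table, an offset of 0, no background correction, median centring, quantile normalization of average intensities, no filter and a strict filter on dim probes, outlier spots kept, the brightest probe per gene, a probe-level fit, dye as a covariate, either array of replicate 1 alone, separate channels with no replicate block, eBayes with trend and robust moderation, an adjusted p of 0.1, a 2-fold minimum, windows of 1 Mb and 5 Mb, and leaving out each replicate. The mean signal, a correction by blocks of array position and the slide as a covariate were chosen after seeing the data.

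The pipeline was tested on simulated data with known changes in 277 of 13685 genes. At true changes of 1.5-fold, 2-fold, 3-fold and 4-fold, 54%, 96%, 100% and 100% of 50 genes each were recovered, with median log2 estimates of 0.50, 0.84, 1.37 and 1.70. Of 185 calls, 7 were false (3.78%). A list shifted by 0.3 on the log2 scale passed with camera at the preset correlation and with fry, but not with an estimated correlation (adjusted p = 0.178). Other lists past the threshold numbered 0 with camera and 1 with fry. The simulation drew the noise of each gene independently, with a smaller dye effect than the SD of 0.22 measured here. In the data, lists such as the major sperm proteins had an estimated correlation of 0.96. The simulated rates of recovery and of false calls may therefore not hold for these data.

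The number of arrays limits the precision. The result of 1 member of the list of longevity regulators, and the counts of that list that rest on it, are not reported here. Probes without a gene name were left out of the gene tests, and control spots were left out of the fit apart from spike-ins used to compare the arrays.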

Results

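Transcript levels of 2 genotypes of the nematode Caenorhabditis elegans were compared on 4 arrays with Cy5 and Cy3 as the dyes. One genotype was isp-1(qm150), a mutant in the Rieske iron-sulfur protein of mitochondrial complex III, and the other was the double mutant isp-1(qm150);ceh-23(ms23), which also carried the ms23 allele of the homeodomain gene ceh-23. All animals were synchronized mid-L4 larvae grown at 20 C on OP50 bacteria. Every array held both genotypes, and the arrays came from 3 biological replicates. Replicate 1 was measured on a pair of arrays with the dyes exchanged, which were averaged, so n = 3 for every ratio. The median signal of the 43803 non-control spots lay between 109.5 and 216 in Cy5 and between 164 and 258.5 in Cy3, over a local background of 59.5 to 61 and 38 to 63. Between 62.4% and 77.5% of the spots were well above background in the double mutant and between 62.2% and 78.4% in isp-1. No spot was saturated. After a filter on dim probes, 13685 genes were tested. A positive log2 ratio means a higher level in the double mutant. The number of replicates limits the precision of every value.

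The comparison asked which transcripts depend on ceh-23 when the electron transport chain is impaired by isp-1. CEH-23 mediates part of the long life of isp-1 animals. The single ceh-23 probe had a log2 ratio of -0.09 (SD 0.10, n = 3, limma adjusted p = 0.529) and was well above background on 2 of the 4 arrays in each genotype, with a median signal of 87 in Cy5 and 99.5 in Cy3. Over the other settings the ceh-23 ratio ran from -0.44, from the scanner's log ratios, to -0.04, without replicate 2, and it passed under none. The array files do not say where the probe lies relative to the ms23 lesion, so its ratio checks neither genotype. The 2 isp-1 probes, a gene mutated in both genotypes, had log2 ratios of 0.01 (SD 0.21, adjusted p = 0.971) and 0.15 (SD 0.03, adjusted p = 0.26).

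The double mutant had lower levels of yolk protein, sperm and oocyte transcripts, a lower signal of the single probe of the mitochondrial import receptor gene tomm-70, and higher levels of a few detoxification and hypoxia-response transcripts, while cuticle collagens moved in both directions (6 rose and 12 fell). Each sample held 1 genotype at 1 stage, so a stage difference between the samples cannot be told apart from an effect of genotype. At an adjusted p of 0.05, 5 of 6 vitellogenin, 10 of 24 major sperm protein, 6 of 51 spermatogenesis and 13 of 33 germline and oogenesis genes fell. These 4 lists passed in camera with a preset inter-gene correlation but not with an estimated one (camera adjusted p = 0.436 to 0.476), with which no list passed. In limma, 461 of the 13685 genes passed an adjusted p of 0.05, of which 106 rose and 355 fell, and 199 of the 461 differed by at least 2-fold. Of the 461 genes, 460 had the same sign on all 4 arrays. At an unadjusted p of 0.05, 4911 genes passed, where chance alone gives 684. Of the 461 adjusted values, 459 lay between 0.049 and 0.05, so the count sits at the edge of the threshold. It was 103 without replicate 1, 1 without replicate 2 and 5939 without replicate 3, and with median centring in place of loess it was 0 in limma, where 1476 genes passed an unadjusted p of 0.05. The balance of directions also moved, with 758 genes higher and 976 lower from the scanner's own log ratios, and 1458 higher and 431 lower with a variance trend and robust moderation. A description that uses no variance estimate counted 1268 genes with the same sign on all 4 arrays and a mean ratio of at least 1.5-fold, 188 higher and 1080 lower. With the sign of replicate 1, 2 or 3 turned, the same count was 2, 13 and 86.

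The lowest ratio belonged to tomm-70 (ZK370.8, chromosome III), the gene for the TOM70 receptor of the outer mitochondrial membrane. The signal of its single probe was 5.42-fold lower in the double mutant, with a log2 ratio of -2.44 (SD 0.13, n = 3, adjusted p = 0.0043), and the 4 arrays gave -2.83, -2.17, -2.29 and -2.52. The yolk protein gene vit-3 (F59D8.1) was 4.52-fold lower, with a log2 ratio of -2.18 (SD 1.06). Among the 10 lowest were 4 genes that neighbour each other on chromosome X in the WBcel235 annotation. These were stha-3 at -2.23 (SD 0.90), ule-5 at -2.04 (SD 0.73), Y62H9A.3 at -2.01 (SD 0.73) and Y62H9A.4 at -1.98 (SD 0.75). The ule-5 gene is named for its expression in the uterine lumen. The remaining members of the 10 lowest were Y57G11B.5 at -2.26 (SD 0.98), C10G8.4 at -2.15 (SD 1.15), F14H3.6 at -2.0 (SD 1.07) and D1054.10 at -1.99 (SD 0.80). All of these except tomm-70 had an adjusted p of 0.0494.

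The highest ratio belonged to the cuticle collagen gene col-41 (T10B10.1, chromosome X), which was 2.95-fold higher in the double mutant, with a log2 ratio of 1.56 (SD 0.08, n = 3, adjusted p = 0.0229). A second cuticle collagen gene, col-90 (C29E4.1), was 2.88-fold higher at 1.52 (SD 0.55). The uncharacterized gene ZK757.2 had a log2 ratio of 1.35 (SD 0.28), F45D11.14 of 1.17 (SD 0.28) and T01D3.3 of 1.08 (SD 0.26). The pseudogene C35D6.5 had 1.09 (SD 0.30). The alpha-tubulin gene tba-8 had 1.07 (SD 0.34). The related genes C08E3.13 and C08E3.1 had 1.06 (SD 0.44) and 1.00 (SD 0.43), and K10D3.4 had 1.04 (SD 0.48). All of these except col-41 had an adjusted p of 0.0494. The 20 genes named here kept their direction under every setting that tested them. Without replicate 2, 19 of the 20 no longer passed, with adjusted p from 0.142 for col-41 to 0.168 for C10G8.4, while tomm-70 had 0.0113. With median centring none of the 20 passed, and tomm-70 had an adjusted p of 0.284. Without a filter on dim probes, with outlier spots kept and with separate channels, 19 of the 20 no longer passed in each, while without background correction and with the mean signal, which was chosen after seeing the data, 18 no longer passed in each. With trend and robust moderation 7 no longer passed, among them tomm-70 (adjusted p = 0.0643). Without replicate 1, tba-8 (adjusted p = 0.0563), C08E3.13 (0.0512), K10D3.4 (0.0911) and C08E3.1 (0.069) no longer passed.

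**Figure D1:**
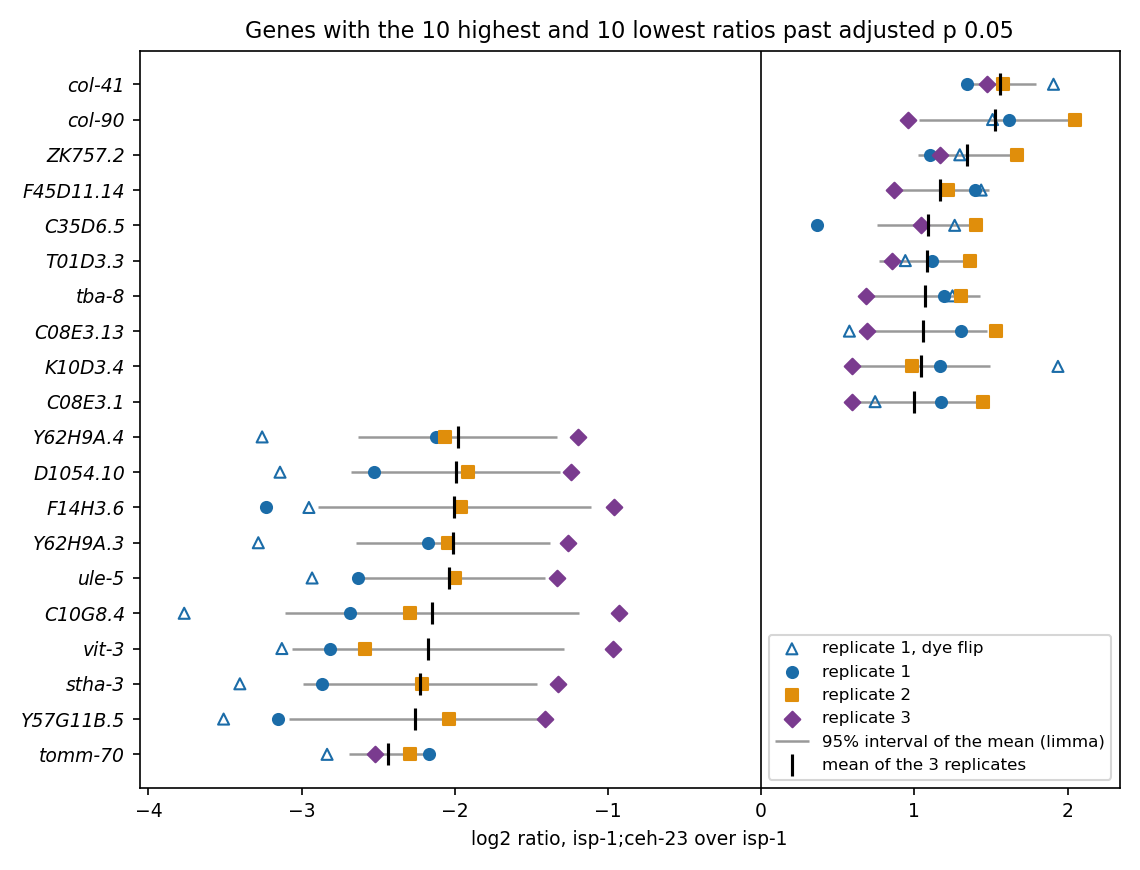
Log2 ratio of double mutant over isp-1 for the 20 named genes, with 1 point per array, the mean of the 3 replicates and its 95% limma confidence interval. The 4 arrays of tomm-70 lie between -2.83 and -2.17, and those of col-41 between 1.34 and 1.91.

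Groups of genes were tested as 48 lists of pathways, gene families and markers of cell types. With limma's camera at a preset inter-gene correlation of 0.01, 25 of the 47 lists large enough to test passed an adjusted p of 0.05, 20 of them higher and 5 lower in the double mutant. With a correlation estimated for each list, 0 passed in camera and 1 had an unadjusted p under 0.05. That setting may have little power with 3 replicates, since the simulated list with a known shift also failed it (camera adjusted p = 0.178). The mitochondrial unfolded protein response, with an estimated correlation of -0.08, had the same camera adjusted p of 0.436 as the major sperm proteins, with 0.959. Failing it therefore does not by itself show that correlation between genes accounts for a list's shift. With fry, which asks whether the genes of a list move on balance one way, 2 passed and 20 had an unadjusted p under 0.05. The sign of the median, the mean and the test differed in 7 lists, none of which passed. No list that passed with the preset correlation changed its direction under another setting. When 1 replicate was left out, the median of 7 of the 25 lists that passed and of 18 of the 22 that did not moved by over 1.5-fold.

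Transcripts tied to reproduction were lower in the double mutant. All 6 vitellogenin genes, which encode the yolk proteins and are transcribed in the intestine, had negative ratios, with a list median of -1.87 (adjusted p = 0.000133). Over all genes 5 fell and 1 did not pass, and adjusted over the list alone 6 fell. Examples were vit-5 at -1.80 (SD 0.75), vit-1 at -1.93 (SD 0.86), vit-3 at -2.18 (SD 1.06) and vit-6 at -1.39 (SD 0.65). The vitellogenin list had an adjusted p = 0.436 with an estimated correlation, which was 0.977. The 24 major sperm protein genes, which encode the cytoskeletal and signalling protein of nematode sperm, had a median of -1.2 (adjusted p = 2.9e-11). Of these, 10 fell and 14 did not pass over all genes, and 24 fell adjusted over the list alone, with msp-36 at -1.21 (SD 0.53) and msp-50 at -1.24 (SD 0.55). The members moved together, with an interquartile range of -1.24 to -1.155 and an estimated correlation of 0.959, so these counts are not of independent genes. Whether each probe reads 1 gene alone was not tested. This list had an adjusted p = 0.436 with an estimated correlation.

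The 33 germline and oogenesis genes had a median of -0.78 (adjusted p = 7.3e-13), and 13 fell and 20 did not pass over all genes, while 33 fell adjusted over the list alone. The list had an adjusted p = 0.436 with an estimated correlation. Among its members were puf-5, for a Pumilio-family RNA-binding protein of oogenesis, at -1.90 (SD 0.71), the germline helicase gene glh-2 at -0.98 (SD 0.31), spn-4, for a maternal RNA-binding protein, at -1.52 (SD 0.61), and the eggshell gene cbd-1 at -1.07 (SD 0.40). The 51 spermatogenesis genes had a median of -0.51 (adjusted p = 2.0e-11), with 6 that fell and 45 that did not pass over all genes, and 33 that fell adjusted over the list alone. This list had an adjusted p = 0.476 with an estimated correlation. Its members ssp-33 and msd-3 had -0.86 (SD 0.29) and -1.19 (SD 0.54). The size of the difference varied between replicates, since the major sperm proteins had medians of -1.83, -1.29 and -0.52 in replicates 1, 2 and 3, and the vitellogenins had -2.72, -1.99 and -0.90. Replicate 1 was on one slide and replicates 2 and 3 were on the other, where the 4 lists had medians of -0.91 (major sperm proteins), -1.50 (vitellogenins), -0.70 (germline and oogenesis) and -0.42 (spermatogenesis).

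**Figure D2:**
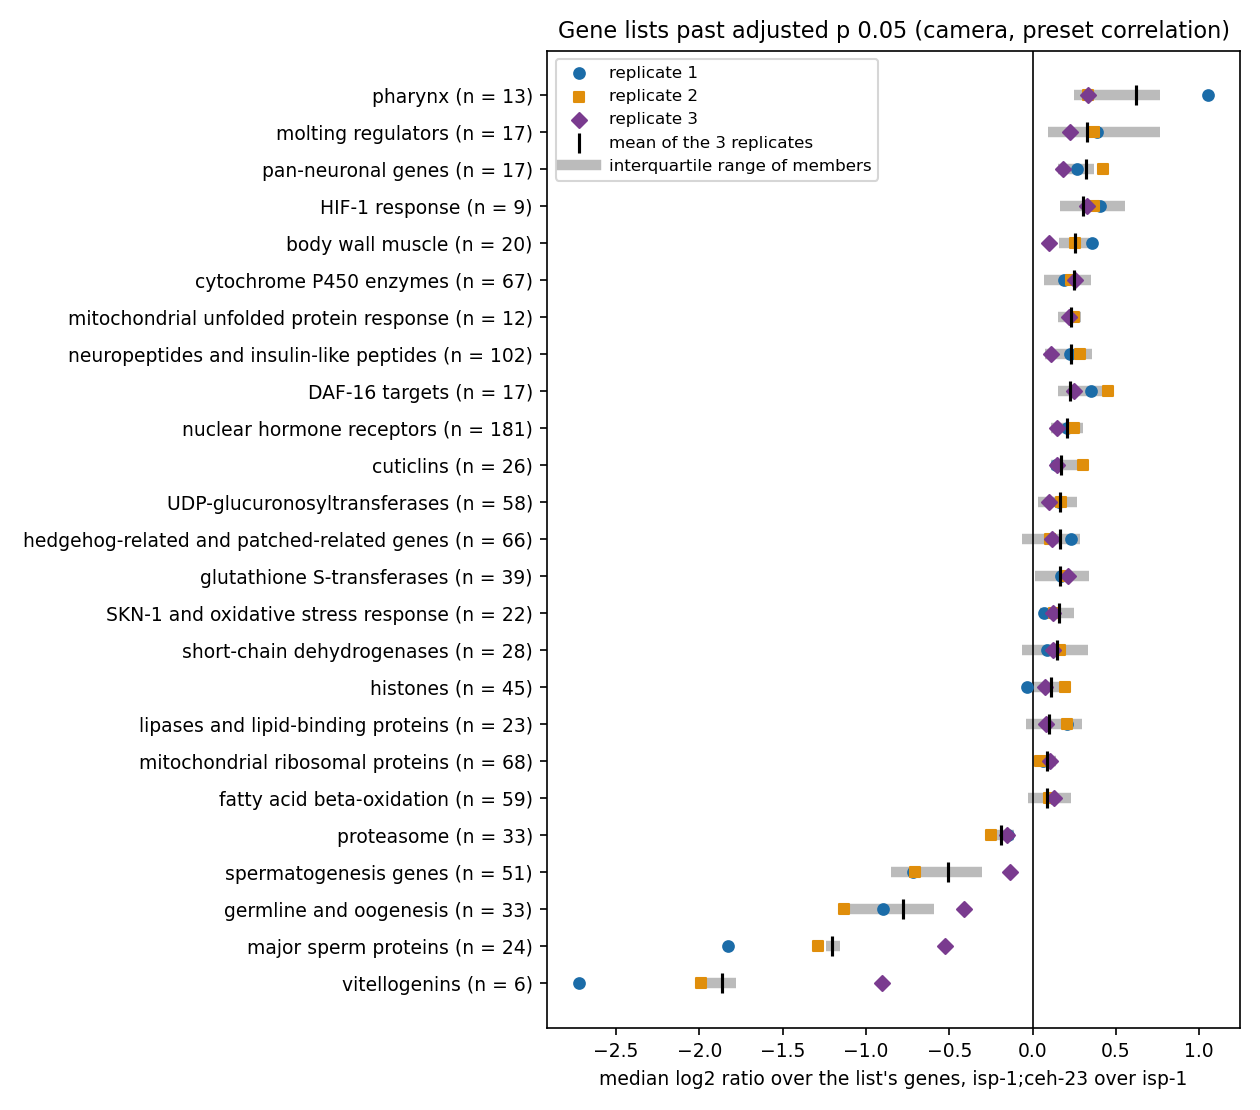
Median log2 ratio of double mutant over isp-1 of the genes in each list, with 1 point per replicate and a bar for the interquartile range of the members. The vitellogenins, the major sperm proteins, the germline and oogenesis genes and the spermatogenesis genes have list medians of -1.87, -1.2, -0.78 and -0.51.

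Lists of genes for the metabolism of foreign compounds had small positive medians and passed with the preset correlation, while few of their members passed over all genes. Among the 6 lists of somatic cell types, pharynx (median 0.62, 0.33 without replicate 1), pan-neuronal (0.32) and body wall muscle (0.25, 0.17 without replicate 1) passed with the preset correlation but not with an estimated one. The lists of hypodermis (0.29, 0.07 without replicate 2), intestine (0.10) and ciliated sensory neurons (0.06) did not pass. The 67 cytochrome P450 genes had a median log2 ratio of 0.25 (adjusted p = 4.3e-07), with 5 that rose and 62 that did not pass over all genes, and 7 that rose and 2 that fell adjusted over the list alone. This list had an adjusted p = 0.436 with an estimated correlation. Its members cyp-14A1, cyp-14A4 and cyp-33C8 had 0.70 (SD 0.11), 0.74 (SD 0.21) and 0.63 (SD 0.11). The 58 UDP-glucuronosyltransferase genes had a median of 0.17 (adjusted p = 0.00018), and 1 rose and 57 did not pass over all genes, with 1 that rose adjusted over the list alone. This was ugt-2 at 0.66 (SD 0.15), while ugt-63 had -0.89 (SD 0.42, adjusted p = 0.0501), and the list had an adjusted p = 0.436 with an estimated correlation. Of 39 glutathione S-transferase genes (median 0.16, adjusted p = 0.00023), 2 rose and 37 did not pass over all genes, and 5 rose adjusted over the list alone. The genes that rose were gst-24 at 0.67 (SD 0.13) and gst-14 at 0.70 (SD 0.24), and the list had an adjusted p = 0.436 with an estimated correlation and 0.0488 with fry. Of 28 short-chain dehydrogenase genes (median 0.14, adjusted p = 0.0216), 2 rose and 26 did not pass over all genes, and 6 rose and 2 fell adjusted over the list alone. They were dhs-29 at 0.67 (SD 0.12) and dhs-4 at 0.78 (SD 0.26), and the list had an adjusted p = 0.436 with an estimated correlation.

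The 181 nuclear hormone receptor genes, a family of ligand-regulated transcription factors that is large in nematodes, had a median of 0.21 (adjusted p = 1.5e-11). Over all genes 3 rose, 1 fell and 177 did not pass, and adjusted over the list alone 3 rose and 1 fell. The list had an adjusted p = 0.436 with an estimated correlation. The receptor genes that rose were nhr-25, a regulator of molting and epidermal fate, at 0.79 (SD 0.15), nhr-61 at 0.90 (SD 0.28) and nhr-155 at 0.84 (SD 0.30), and nhr-2 fell, at -0.70 (SD 0.21). The 49 homeobox genes, the class to which ceh-23 belongs, did not pass (median 0.05, adjusted p = 0.341), and none of them passed in limma over all genes or adjusted over the list alone, where 14 did at an unadjusted p of 0.05. Their smallest p-values belonged to ceh-83 at -0.96 (SD 0.53, adjusted p = 0.0514) and ceh-49 at -1.03 (SD 0.59, adjusted p = 0.0528).

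Lists of stress programs tied to mitochondria and lifespan had small positive medians and passed with the preset correlation, while few of their members passed over all genes. Camera compares a list with all other tested genes, many of which fell. Lists of other functions passed with medians of like size, such as nuclear hormone receptors (0.21) and neuropeptides and insulin-like peptides (0.23), while others, such as ribosomal proteins (0.02), did not pass. Whether the shift is particular to stress genes was not tested. Among 9 genes of the response to the hypoxia factor HIF-1 (median 0.30, adjusted p = 0.00333), 2 rose and 7 did not pass over all genes, and 4 rose adjusted over the list alone. They were sqrd-1, for sulfide:quinone oxidoreductase, at 0.68 (SD 0.09) and cysl-2, for a cysteine synthase-like enzyme, at 0.65 (SD 0.10), while nhr-57 had 0.55 (SD 0.45, adjusted p = 0.0911). The list had an adjusted p = 0.436 with an estimated correlation. Among 17 targets of the FOXO factor DAF-16 (median 0.22, adjusted p = 0.00494), 2 rose and 15 did not pass over all genes, and 6 rose and 1 fell adjusted over the list alone. They were the superoxide dismutase gene sod-3 at 0.76 (SD 0.05) and the metallothionein gene mtl-1 at 0.94 (SD 0.29), while sip-1 had -0.88 (SD 0.55, adjusted p = 0.0578), and the list had an adjusted p = 0.436 with an estimated correlation.

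The 12 genes of the mitochondrial unfolded protein response had a median of 0.23 (adjusted p = 0.00364), although none of them passed in limma over all genes or adjusted over the list alone, where 5 did at an unadjusted p of 0.05. The chaperone genes hsp-60, dnj-10 and hsp-6 had 0.37 (SD 0.18, adjusted p = 0.0813), 0.30 (SD 0.07, adjusted p = 0.0943) and 0.30 (SD 0.19, adjusted p = 0.125). The list had an adjusted p = 0.436 with an estimated correlation and 0.0488 with fry. Of 22 genes of the oxidative stress response to SKN-1 (median 0.16, adjusted p = 0.0104), sod-3 rose and 21 did not pass over all genes, and 1 rose adjusted over the list alone, with gst-10 at 0.42 (SD 0.13, adjusted p = 0.0619). For the list, camera gave an adjusted p = 0.436 with an estimated correlation, and 0.0538 from the scanner's log ratios, and without replicate 2 the median was 0.09. The 48 nuclear genes for subunits of the electron transport chain and ATP synthase did not pass (median 0.06, adjusted p = 0.166), with none past the threshold over all genes or adjusted over the list alone and 4 at an unadjusted p of 0.05, and ucr-2.3 had -0.57 (SD 0.22, adjusted p = 0.0514).

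Regulators that act with CEH-23 or in related longevity pathways did not pass as groups. The 24 genes of AMP-activated kinase subunits and longevity regulators had a median of 0.00 (adjusted p = 0.754). The kinase subunit genes aak-1 and aakg-4 had -0.43 (SD 0.30, adjusted p = 0.0899) and 0.31 (SD 0.12, adjusted p = 0.0942). Among 6 genes of the p53 homolog CEP-1 and apoptosis (median -0.27, adjusted p = 0.193), 1 fell and 5 did not pass over all genes, and 1 rose and 2 fell adjusted over the list alone. The caspase gene ced-3 fell, at -0.88 (SD 0.33), and cep-1 itself had -0.53 (SD 0.32, adjusted p = 0.0702). None of the genes of the heat shock response (17 genes, median 0.15, adjusted p = 0.105) or of the endoplasmic reticulum unfolded protein response (18 genes, median 0.08, adjusted p = 0.135) passed over all genes or adjusted over the list alone, although 3 of each did at an unadjusted p of 0.05, with hsp-43 at -0.64 (SD 0.31, adjusted p = 0.0545) and hsp-4 at -0.46 (SD 0.24, adjusted p = 0.0713). Without replicate 3, the heat shock list passed (adjusted p = 0.00666).

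Lists of pharynx, body wall muscle and pan-neuronal genes had positive medians and passed with the preset correlation, while none of their genes passed over all genes. The 13 pharynx genes had a median of 0.62 (adjusted p = 0.000133), with 0 that passed in limma over all genes (8 at an unadjusted p of 0.05) and 8 that rose adjusted over the list alone. The pharynx medians of replicates 1, 2 and 3 were 1.05, 0.33 and 0.33, and without replicate 1 the median was 0.33. The pharyngeal myosin gene myo-2 had 0.99 (SD 0.70, adjusted p = 0.0649) and the troponin C gene tnc-2 had 0.79 (SD 0.48, adjusted p = 0.0585), and the list had an adjusted p = 0.462 with an estimated correlation. The 20 body wall muscle genes had a median of 0.25 (adjusted p = 0.000133), and none passed over all genes or adjusted over the list alone, where 7 did at an unadjusted p of 0.05. The twitchin gene unc-22 had 0.49 (SD 0.14, adjusted p = 0.0531) and the myosin gene myo-3 had 0.48 (SD 0.27, adjusted p = 0.072), with an adjusted p = 0.436 for the list with an estimated correlation and a median of 0.17 without replicate 1. The 17 pan-neuronal genes had a median of 0.32 (adjusted p = 7.4e-05), with none past the threshold over all genes (9 at an unadjusted p of 0.05) and 9 that rose adjusted over the list alone. Examples were the proprotein convertase gene egl-3 at 0.46 (SD 0.10, adjusted p = 0.0547) and the SNAP-25 gene ric-4 at 0.47 (SD 0.16, adjusted p = 0.0575), and the list had an adjusted p = 0.436 with an estimated correlation.

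The 102 genes of neuropeptides and insulin-like peptides had a median of 0.23 (adjusted p = 2.8e-08), with 2 that rose and 100 that did not pass over all genes, and 19 that rose and 3 that fell adjusted over the list alone. The insulin-like gene ins-35 rose, at 0.78 (SD 0.23), and so did the FMRFamide-like gene flp-5, at 0.66 (SD 0.23), while nlp-26 had -0.63 (SD 0.24, adjusted p = 0.0502). For the list, camera gave an adjusted p = 0.436 with an estimated correlation. The 21 ciliated sensory neuron genes did not pass (median 0.06, adjusted p = 0.0776), nor did any of them over all genes or adjusted over the list alone (3 at an unadjusted p of 0.05), and dyf-4 had 0.49 (SD 0.29, adjusted p = 0.0724). From the scanner's log ratios, the ciliated list passed (adjusted p = 0.011). Only 4 genes of the AIY interneuron list were measured, too few to test, with cho-1 at 0.42 (SD 0.16, adjusted p = 0.0677) and kal-1 at 0.54 (SD 0.40, adjusted p = 0.0845). Adjusted over the list alone, 2 of these rose, and over all genes none did (3 at an unadjusted p of 0.05). Of 15 intestine genes (median 0.10, adjusted p = 0.0801), mtl-1 rose and 14 did not pass over all genes, and 1 rose adjusted over the list alone. The intestine list passed without replicate 1 (median 0.07, adjusted p = 0.0485) and without replicate 2 (median 0.17, adjusted p = 0.0404), and without replicate 3 it did not (median 0.02, adjusted p = 0.102). Of 8 hypodermis genes (median 0.29, adjusted p = 0.144), nhr-25 rose and 7 did not pass over all genes, and 4 rose and 1 fell adjusted over the list alone, and the median was 0.07 without replicate 2, with the adult collagen gene col-19 at -1.56 (SD 0.87, adjusted p = 0.0501).

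Lists of molting regulators, hedgehog-related and patched-related genes and cuticlins had positive medians and passed with the preset correlation, while cuticle collagens moved in both directions. The 17 molting regulators had a median of 0.32 (adjusted p = 5.9e-05), and nhr-25 rose and 16 did not pass over all genes, while 9 rose adjusted over the list alone. The matrix genes noah-1 and fbn-1 had 0.82 (SD 0.38, adjusted p = 0.0501) and 0.85 (SD 0.48, adjusted p = 0.0545), and the list had an adjusted p = 0.436 with an estimated correlation. Among 66 hedgehog-related and patched-related genes (median 0.17, adjusted p = 0.000191), 4 rose and 62 did not pass over all genes, and 11 rose adjusted over the list alone. These were grd-13 at 0.94 (SD 0.27), qua-1 at 0.52 (SD 0.05), grl-24 at 0.77 (SD 0.33) and wrt-10 at 0.90 (SD 0.42), and the list had an adjusted p = 0.436 with an estimated correlation and a median of 0.10 without replicate 1. The 26 cuticlin genes had a median of 0.17 (adjusted p = 0.000487) and none passed over all genes or adjusted over the list alone (8 at an unadjusted p of 0.05), with cutl-3 at 0.47 (SD 0.13, adjusted p = 0.0553), and the list had an adjusted p = 0.436 with an estimated correlation. The 151 cuticle collagens did not pass as a list (median -0.08, adjusted p = 0.812), and the direction of their test turned under 4 settings. Over all genes, 6 collagens rose, 12 fell and 133 did not pass, and adjusted over the list alone 29 rose and 36 fell. Besides col-41 and col-90, col-169 rose at 0.89 (SD 0.17), and col-137 fell at -0.86 (SD 0.17).

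Among genes for growth and metabolism, the 33 proteasome subunit genes had a median of -0.19 (adjusted p = 0.00137), and none passed over all genes or adjusted over the list alone, where 8 did at an unadjusted p of 0.05. The subunit genes pas-5 and rpt-1 had -0.35 (SD 0.12, adjusted p = 0.0787) and -0.30 (SD 0.05, adjusted p = 0.0924). The proteasome list had an adjusted p = 0.436 with an estimated correlation and 0.0709 without replicate 3. The 68 mitochondrial ribosomal protein genes had a median of 0.09 (adjusted p = 0.0212), with none past the threshold over all genes or adjusted over the list alone (2 at an unadjusted p of 0.05), and mrpl-41 had 0.29 (SD 0.12, adjusted p = 0.106). For the list, camera gave an adjusted p = 0.436 with an estimated correlation and 0.147 with median centring, and without replicate 3 the median was 0.04. The 45 histone genes had a median of 0.11 (adjusted p = 0.0406), none passed over all genes or adjusted over the list alone (3 at an unadjusted p of 0.05), and his-24 had 0.45 (SD 0.34, adjusted p = 0.0924). The histone list had an adjusted p = 0.502 with an estimated correlation and 0.377 without replicate 2, where the median was 0.06, and it passed under 10 of 19 other settings of the fit. The 77 ribosomal protein genes did not pass (median 0.02, adjusted p = 0.233), and none did over all genes or adjusted over the list alone (4 at an unadjusted p of 0.05), with rpl-42 at -0.41 (SD 0.34, adjusted p = 0.11). With median centring, the ribosomal protein list passed (adjusted p = 0.00134).

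The 59 genes of fatty acid beta-oxidation had a median of 0.08 (adjusted p = 0.0254), with 0 that passed in limma over all genes (20 at an unadjusted p of 0.05) and 3 that rose and 3 that fell adjusted over the list alone. The acyl-CoA synthetase genes acs-16 and acs-6 had 0.54 (SD 0.15, adjusted p = 0.0502) and -0.62 (SD 0.29, adjusted p = 0.0536). For the list, camera gave an adjusted p = 0.436 with an estimated correlation, 0.0592 without replicate 2 and 0.071 without replicate 3. Of 23 lipase and lipid-binding protein genes (median 0.10, adjusted p = 0.0259), far-7 rose at 0.93 (SD 0.38) and 22 did not pass over all genes, and 1 rose adjusted over the list alone. The list had an adjusted p = 0.476 with an estimated correlation and 0.0812 without replicate 1, and its median was 0.17 without replicate 2. Of 22 genes of glycolysis, fermentation and gluconeogenesis (median 0.11, adjusted p = 0.161), 2 fell and 20 did not pass over all genes, and 1 rose and 2 fell adjusted over the list alone. They were the glyceraldehyde-3-phosphate dehydrogenase genes gpd-4 at -1.13 (SD 0.45) and gpd-1 at -0.54 (SD 0.10). None of the 21 genes of the TCA and glyoxylate cycles (median 0.13, adjusted p = 0.0643) or of the 17 genes of fatty acid desaturation and elongation (median 0.00, adjusted p = 0.669) passed over all genes or adjusted over the list alone. At an unadjusted p of 0.05, 5 and 4 of them did, with icl-1 at 0.42 (SD 0.09, adjusted p = 0.0579) and fat-7 at -0.58 (SD 0.24, adjusted p = 0.0532). The TCA list passed without replicate 2 (median 0.14, adjusted p = 0.0153) and did not without replicate 1 (median 0.03, adjusted p = 0.311).

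Families of immunity and of other large classes had single members that passed while the lists did not. Of 66 antimicrobial peptide and lysozyme genes (median 0.05, adjusted p = 0.225), 3 fell and 63 did not pass over all genes, and 2 rose and 6 fell adjusted over the list alone. The 3 were the invertebrate-type lysozyme genes ilys-6 at -0.93 (SD 0.17), ilys-3 at -0.89 (SD 0.23) and ilys-2 at -0.97 (SD 0.30). Of 109 C-type lectin genes (median 0.03, adjusted p = 0.542), 1 rose, 7 fell and 101 did not pass over all genes, and 4 rose and 8 fell adjusted over the list alone. The lectin gene clec-17 rose at 0.86 (SD 0.15), and clec-87 fell at -1.59 (SD 0.62). Of 50 transthyretin-related genes (median 0.04, adjusted p = 0.729), 3 fell and 47 did not pass over all genes, and 5 rose and 13 fell adjusted over the list alone, with ttr-42 at -1.71 (SD 0.69) and ttr-51 at -0.81 (SD 0.27). Of 46 genes of nematode-specific peptide families (median -0.07, adjusted p = 0.202), 4 fell and 42 did not pass over all genes, and 2 rose and 14 fell adjusted over the list alone. The 4 were nspd-10 at -1.06 (SD 0.39), nspd-1 at -1.15 (SD 0.55), nspd-6 at -0.99 (SD 0.46) and nspd-3 at -1.18 (SD 0.59), and the list passed without replicate 1 (adjusted p = 0.0138).

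Of 61 genes with MATH and BATH domains, found in adaptors of ubiquitin ligases, 1 fell and 60 did not pass over all genes (median -0.24, adjusted p = 0.0785), and 2 rose and 15 fell adjusted over the list alone. The gene that fell was bath-28 at -0.69 (SD 0.27), and from the scanner's log ratios the list passed (adjusted p = 0.0457). Of 153 F-box genes, which belong to the same kind of ligase (median 0.03, adjusted p = 0.97), 4 fell and 149 did not pass over all genes, and 1 rose and 6 fell adjusted over the list alone. They were fbxa-210 at -0.73 (SD 0.15), fbxa-215 at -1.13 (SD 0.41), fbxa-107 at -0.63 (SD 0.15) and fbxc-50 at -1.58 (SD 0.80). Of 111 chemoreceptor genes (median 0.03, adjusted p = 0.233), 1 rose, 3 fell and 107 did not pass over all genes, and 2 rose and 3 fell adjusted over the list alone, with src-2 at 0.73 (SD 0.13) and sra-5 at -0.69 (SD 0.13). The 8 genes for SCP-like extracellular proteins did not pass (median 0.12, adjusted p = 0.542), with none past the threshold over all genes (6 at an unadjusted p of 0.05) and 3 that rose and 3 that fell adjusted over the list alone, and vap-2 had -1.06 (SD 0.74, adjusted p = 0.0632). The direction of the test turned under other settings for the C-type lectins, the transthyretin-related genes, the F-box genes, the desaturation and elongation genes and the longevity regulators.

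A strain built by crossing can carry a stretch of the donor chromosome around the crossed-in mutation, so the place of the changed genes was compared with ceh-23, which lies on chromosome III. Genes on chromosome III were less often among the changed ones. Of 2141 tested genes there, 34 changed (1.59%), against 427 of 11544 elsewhere (3.70%), an odds ratio of 0.42 (95% confidence interval 0.286 to 0.598, two-sided Fisher's exact p = 9.9e-08). The changed genes of chromosome III included tomm-70, col-90 and ZK757.2. Most changed genes fell (355 of 461), among them genes of the reproductive lists, which move together. A low share of changed genes can therefore not exclude a donor stretch with few altered genes. Fisher's exact test takes genes as independent, while lower genes often lay side by side. Its p-values are therefore likely too small and its intervals too narrow. Within 2 Mb of ceh-23 in the WBcel235 annotation, 12 of 751 genes changed (odds ratio 0.452, Fisher's exact p = 0.00344). Without replicate 3, the odds ratio was 0.915 (Fisher's exact p = 0.0641) for the chromosome and 1.02 (Fisher's exact p = 0.791) within 2 Mb, and within 2 Mb it was 0.515 (Fisher's exact p = 0.38) without replicate 1. Without a filter on dim probes, concordant genes had an odds ratio of 0.893 (Fisher's exact p = 0.222) for the chromosome, and with dye as a covariate changed genes had 1.04 (Fisher's exact p = 0.624) within 2 Mb.

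The arrays differed in how closely they followed each other across genes, which are not independent replicates. The 2 dye-flip arrays of replicate 1, which held the same RNA, had a Pearson correlation of 0.665 and a Spearman correlation of 0.541 across 13685 genes, and from the scanner's log ratios the Pearson value was 0.866. The dye-flip array and replicate 2, which hold different RNA in the same dye orientation, had a Pearson correlation of 0.814, and the first array of replicate 1 and replicate 2 had 0.736. With replicate 3, the first array of replicate 1 had 0.572 in the same dye orientation, and the dye-flip array had 0.587 in the opposite one. Replicates 1 and 2 had a Pearson correlation of 0.851, replicates 1 and 3 of 0.635, and replicates 2 and 3 of 0.555. The ratios of replicate 3 were smaller, with an SD across probes of 0.251 against 0.553, 0.495 and 0.482 on the other arrays. Genes of the reproductive lists had a median of -0.32 in replicate 3 and -1.1 in the mean of replicates 1 and 2, while genes of the 8 stress and detoxification lists that passed had 0.17 and 0.20. Other lists were also smaller in replicate 3, with medians of 0.36, 0.25 and 0.10 in replicates 1, 2 and 3 for body wall muscle, 0.22, 0.29 and 0.11 for neuropeptides and insulin-like peptides, and 0.28, 0.13 and -0.15 for the heat shock response. The log2 ratios of tomm-70 and col-41 in replicate 3 were -2.52 and 1.47. The difference between the dye-flip arrays of replicate 1, which holds array and position effects besides that of the dye, gave a dye effect with an SD across genes of 0.22, against 0.486 for the genotype effect, and 0.188 with position blocks. The range of median log2 ratios across 10 bands of the array was 0.437 and 0.493 on these arrays and 0.215 and 0.104 in replicates 2 and 3.

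**Figure D3:**
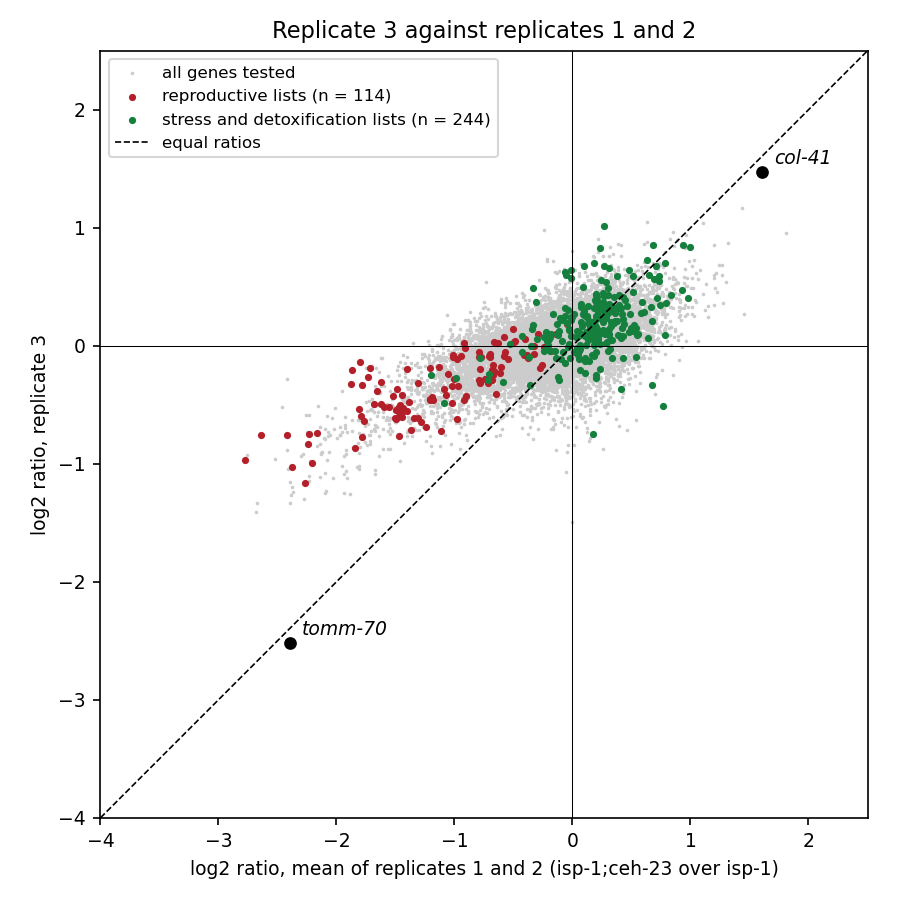
Log2 ratio of double mutant over isp-1 in replicate 3 against the mean of replicates 1 and 2, with 1 point per gene, the 114 genes of the reproductive lists and the 244 genes of the 8 stress and detoxification lists that passed in colour. The reproductive genes have medians of -0.32 and -1.1 on the vertical and horizontal axes, and tomm-70 and col-41 are marked.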

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

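The test of probes without a gene name was chosen only after the gene results were seen. Of 2342 kept probes that could not be given a gene name, and that no comparison above uses, 100 had the same sign on all 4 arrays and at least a 1.5-fold mean ratio, 19 higher and 81 lower in the double mutant. With the sign of 1 replicate turned, the highest count was 10. The log2 ratios of the 100 probes ran from -2.03 to 1.72, and no explanation was tested.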

How the results depend on the processing

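The mean signal, the position blocks and the slide covariate were chosen only after the result was seen. All 461 changed genes kept their direction under every setting that tested them. For the 460 with the same sign on all 4 arrays, settings that only left out or reweighted arrays could not turn the direction. The number of changed genes was 3447 at an adjusted p of 0.1, 1890 with a probe-level fit, 1734 with the scanner's log ratio, 1736 with the series table, 1491 with an offset of 0, 2 without background correction, 0 with median centring in limma (1476 at an unadjusted p of 0.05), 1 without a filter on dim probes, 755 with a strict filter, 1 with outlier spots kept, 963 with the brightest probe, 4151 with dye as a covariate, 733 and 777 from the dye-flip or the first array of replicate 1 alone, 1889 with trend and robust moderation, 2 with the mean signal, 940 with position blocks, 1264 with the slide as a covariate, and 1 to 5939 when 1 replicate was left out. With no replicate block (separate channels, not paired within arrays) 1 gene passed. Leaving out 1 replicate gave fewer genes (103 without replicate 1 and 1 without replicate 2) or more (5939 without replicate 3), so the number of replicates alone does not account for these counts. Apart from the looser threshold, the cause was not tested. Concordant genes numbered 303 at 2-fold, 2394 with the scanner's log ratio and with the series table, 841 with median centring, and 940 to 2428 when 1 replicate was left out.

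Of the lists, 0 passed with an estimated correlation (camera, 1 at an unadjusted p of 0.05), 2 with fry, and 24 to 26 when 1 replicate was left out. Over all lists and settings, 870 results kept their direction and their side of the threshold, 72 lost their call, 26 gained one and 19 turned, where the series table, which repeats the scanner's log ratio, and quantile normalization, which leaves the ratios as they are, were not counted. The ceh-23 ratio ran from -0.44 to -0.04 and passed under none. Where fewer than 20 genes changed, odds ratios are of concordant genes. The odds ratio of chromosome III was 0.893 without a filter and 0.452 to 0.915 when 1 replicate was left out. Within 2 Mb it was 0.661 for 1 Mb, 0.792 with an offset of 0, 0.736 with median centring, 0.931 without a filter, 1.04 with dye as a covariate, and 0.515 to 1.02 when 1 replicate was left out. The correlation of the dye-flip pair was 0.866 with the scanner's log ratio and with the series table. Lists that did not pass turned the direction of their test, with these medians. C-type lectins had 0.0262 with fry, -0.00876 without a filter and -0.0188 to 0.027 when 1 replicate was left out (turned without replicate 2). Transthyretin-related genes had 0.0387 with fry, -0.00247 from the dye-flip array and -0.00989 to 0.0798 when 1 replicate was left out (turned without replicate 1), and longevity regulators had 0.00353 with fry. Desaturation and elongation genes had 0.0249 with the scanner's log ratio and the series table and -0.0239 from the dye-flip array. F-box genes had 0.134 with the scanner's log ratio and the series table, 0.0325 without background correction, 0.00109 without a filter, 0.0278 with outlier spots kept, 0.0386 from the first array of replicate 1 and 0.0561 with the mean signal. Collagens had -0.0621 with median centring, -0.0596 from the dye-flip array, -0.0799 with separate channels and -0.148 to 0.00842 when 1 replicate was left out (turned without replicate 2). The cause was not tested for any of these.

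By the same count the 20 named genes gave 235 values past the threshold and 143 not past it, all in the direction reported, and tomm-70 passed in 17 of 19. Where a setting only left out or reweighted arrays, the choice of these genes fixed their direction. The replicate number and the slide as random blocks could not be fitted, since duplicateCorrelation gave no estimate with 4 and 3 arrays. Signal over background limits ceh-23, above background on 2 of 4 arrays.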

Other observations

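The neighbour, collagen and replicate 3 counts here, and the tests below except that of the number of gene lists under turned signs, were chosen only after the result was seen. Genes named here were chosen after their values were seen. The tests of tomm-70 were set before their outcomes were known, but after its ratio was seen. Lower genes often lay side by side on the chromosome in the WBcel235 annotation. Of the 1080 concordant genes that were lower, 193 pairs were neighbours among the tested genes, against a mean of 92.5 and a highest of 130 in 10000 permutations within chromosomes (permutation p = 1e-04, the smallest they can give). A name stem was shared by 71 of the pairs, either that of a gene family or the start of a sequence name such as D1086. This is no count of related genes, and the share over all neighbours was not taken. The 188 higher genes formed 16 such pairs, against a mean of 2.98 and a highest of 11 (permutation p = 1e-04, the smallest they can give). Runs of lower genes included D1086.17, D1086.11, D1086.6, D1086.10 and D1086.7, with log2 ratios of -1.87 to -0.92, and ZK813.3, ZK813.2, ZK813.7 and ZK813.1, with -1.68 to -0.96. A run of higher genes held the lipocalin-related genes lpr-3, lpr-6, lpr-5 and lpr-4, with 0.62 to 0.76, of which lpr-3 and lpr-6 passed the threshold.

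The log2 ratios of the 151 cuticle collagens had an SD of 0.586, against 0.369 over all genes tested, collagens included, a difference that was not tested. Of the collagens, 15 were concordant and higher while 23 were concordant and lower. In replicate 3, 73 concordant genes had at least 0.75 of their mean log2 ratio in replicates 1 and 2, of which 46 were higher and 27 lower. Besides tomm-70 and col-41, they included sod-3 (0.76), mtl-1 (0.94), nhr-25 (0.79), clec-17 (0.86) and the carboxylesterase gene cest-1.1 (0.92), and the lysozyme genes ilys-3 (-0.89) and ilys-6 (-0.93).

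The signs of the 3 replicates can be turned in 4 patterns, which are too few for a share under 0.05. For changed genes, 1 of the 4 patterns, the real one, gave as many as 461, and the highest of the others gave 0 in limma (480 at an unadjusted p of 0.05). For gene lists past the threshold, 1 of the 4 gave as many as 25, and the highest of the others gave 19.

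Reproductive transcripts were lower in the double mutant in all replicates, with 103 of 114 genes of the 4 lists below 0 on all 4 arrays. Dye bias would turn the sign between dye orientations, but the highest of the 4 array medians was -0.319, and arrays of both orientations were below 0. A smaller share of reproductive tissue in the RNA, with all other tissues alike, would raise the somatic markers alike. The 6 somatic list means differed (permutation p = 0.00048) but not without replicate 1 (permutation p = 0.232) or without the pharynx list (permutation p = 0.156). For the germline and sperm lists this cause can therefore not be told apart here. Vitellogenins are transcribed in the intestine, so a smaller share of reproductive tissue would not lower them. Their median of -1.87 (-2.72, -1.99 and -0.90 in replicates 1, 2 and 3), beside 0.10 for the intestine list, argues against it for these 6 genes. A difference in developmental stage between the samples may account for the pattern. It cannot be told apart from an effect of genotype, because each sample held 1 genotype at 1 stage. In replicate 3, 99.1% of the 114 genes had their log2 ratio of smallest absolute size, so the fall was weakest there. These genes move together, so the share is no count of independent genes. The molting regulators were higher (list median 0.32), and the adult collagen gene col-19 was lower without passing. Neither was tested as a marker of stage. An effect of ceh-23 on the germline stays open and was not tested.

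The log2 ratios of replicate 3 had an SD 0.497 times that of the other replicates' mean. Compression by the array is argued against by the spike-in slope, which was 0.959 times that of the other arrays. Mixing of the RNAs would shrink all ratios alike. The 10 stress and detoxification lists, heat shock and endoplasmic reticulum included, kept 0.779 of their median ratio (95% bootstrap interval 0.615 to 1.03, 275 genes), while reproductive genes kept 0.289 (0.236 to 0.357, 114 genes). With each replicate centred on its median gene, the values were 0.551 (0.422 to 0.741) and 0.321 (0.268 to 0.390). The reproductive genes thus shrank more in this replicate. Mixing would also shrink single large ratios, but tomm-70 had -2.50, -2.29 and -2.52 in replicates 1, 2 and 3. For col-41 the values were 1.63, 1.58 and 1.47. Mixing does not account for these ratios, which are the lowest and the highest of all genes tested and not a set. The bootstrap intervals resample genes and not replicates, though genes of the reproductive lists move together. By themselves they are too narrow to exclude mixing as the whole cause. A smaller difference in stage or reproductive tissue between the samples of replicate 3 may account for part of it, but of 21 other lists past the threshold 12 had an interval that reached that of the reproductive genes, such as body wall muscle at 0.297 (0.160 to 0.585) and neuropeptides and insulin-like peptides at 0.396 (0.227 to 0.522). The labels give no stage finer than mid-L4, so it stays open.

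The ratio of tomm-70 was nearly constant, at -2.50, -2.29 and -2.52 in replicates 1, 2 and 3, and rested on 1 probe. A deletion that takes in its neighbours would lower them too, but the 20 nearest tested genes had a median of -0.0561, a lowest ratio of -0.68 and a highest of 0.25, and none of them changed in limma (3 at an unadjusted p of 0.05). A stretch of donor chromosome around ceh-23 with a variant in tomm-70 may lower its signal. Genes that kept their size in replicate 3 had an odds ratio of 0.242 within 2 Mb of ceh-23 (95% confidence interval 0.00604 to 1.40, Fisher's exact p = 0.188, tomm-70 left out), which rests on too few genes to decide. A variant under the single probe and a true fall of the transcript cannot be told apart here.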
